A study of Mus musculus with 18 samples.

How the data were processed

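RNA of 18 cultures of primary mouse myoblasts was read on 18 Affymetrix Mouse Gene 1.0 ST arrays, 1 array per culture. Per the labels, satellite cell-derived myoblasts were expanded from the hindlimb muscles of 3 male mice, the cells of each mouse were divided over 6 retroviral constructs, and samples with the same replicate number came from the same animal. The deposited values were log2 signals, 1 per probe set and array, which the authors made by RMA in Affymetrix Expression Console. RMA corrects background, makes the distributions of probe signals equal over arrays and summarises the probes of each probe set. The summarised values used here were not equal in distribution: the first quartile over genes ran from 6.797 to 7.203. The version of that software and its summary level were not stated. The values were used as deposited, without a further transformation, and 0 value columns were left unused. Arrays carry no read depth, and their number limits the precision. The deposited table has no detection calls, so a gene without expression cannot be told from a dim gene, and changes of genes with low signal in 1 of the groups are understated.

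The table held 35556 probe sets. The probe sets named by exactly 1 gene symbol, 21789 in number, were used, and the 1621 with several symbols and the 12146 without one were left out of the comparisons because their signal cannot be given to 1 gene. Where a gene had more than 1 probe set, as 999 did, the one with the highest mean over all arrays was kept, which left 19938 genes and no filter on dim ones. Of the named probe sets 21698 had a gene identifier found in the RefSeq annotation of the mouse genome, which served only for gene names and for the order of genes along chromosomes. The human DUX4 transgenes and DUX4c have no probe sets on this array, so their expression was not checked.

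Every comparison came from 1 linear model in limma (version 3.58.1, R version 4.3.3) fitted to all 18 arrays, with the construct as the factor of interest and the mouse as a fixed block, 10 residual degrees of freedom and limma's moderated statistics, which are two-sided. Each of the 5 constructs was compared with the control virus, 4 pairs of constructs were compared with each other, and an F test over the 5 constructs asked for any difference. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 19938 genes of its comparison. Fold thresholds served only for counts of changes of at least 2-fold. Overlaps of called genes were set against the number expected for independent sets, and the covariance of the changes across genes against that in 100 simulations of unchanged groups that shared their controls. Within a mouse the deviations of arrays from their construct's mean had a mean correlation of 0.17, against -0.08 between mice, and 28 of the 45 same-mouse pairs lay above 0.1.

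The comparisons, the 34 gene lists, the processing alternatives and the rule for naming genes were fixed before the data were examined, except where stated otherwise. Of 1564 list entries 1406 were measured. A list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists and the 5 comparisons with control, 170 tests together, and the 4 comparisons between constructs formed a family of their own. Camera with an estimated correlation and limma's fry were run beside it. For each list, members called over all genes and members called when adjusted over the list alone were counted. The named genes were, for each comparison with control, the 12 largest rises and the 12 largest falls among called genes with 1 sign in 3 of 3 mice, up to 4 called members of each list with the largest change, and 12 key genes whatever their value, of which 10 were measured. For pairs of constructs they were the 6 largest differences each way, and for overlaps the 8 genes with the largest smaller change of both. Genes known only by a predicted or clone-derived symbol and olfactory receptors were passed over.

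The model and its calls were tested on simulated data, drawn independently for each gene around its control mean with its residual SD and the mouse differences, with 200 genes changed in each comparison. Of changes of 1 on the log2 scale between 94% and 98% were recovered, of changes of 0.5 between 54% and 64%, and of 185 to 192 calls per comparison 8 to 13 were false. The data had 1834 to 4603 calls against control, among genes that are not independent, so these shares do not carry over to the data. The counts of called genes in each comparison and the genes named by the rule were recomputed without the block, with the mouse as a random block, with a trended and robust prior, without genes below the first quartile of mean signal, with all probe sets, with arrays centred on their median, with arrays quantile-normalized again, with only the 6 arrays of both groups, and without each mouse and each single array. The F test, the overlaps and the number of lists called against control were recomputed in the same ways, except with 6 arrays and without single arrays, and list calls between constructs were not recomputed. Alternatives added after the data had been seen were the median of olfactory receptor genes as a covariate, the omission of the 4 arrays with the lowest first quartile, the list medians after quantile normalization, the list calls under 7 settings, the overlap of truncated DUX4 with DUX4c and the opposite calls other than those of DUX4-VP16 and DUX4-ERD. The splits of the arrays were counted, 10 for each pair of groups and 100 rearrangements of the constructs within mice for the F test. Plots were drawn with matplotlib (version 3.10.9) in Python (version 3.11.15).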

Results

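Gene expression was measured in mouse myoblasts grown from hindlimb satellite cells, the stem cells of skeletal muscle. The myoblasts of each of 3 male C57Bl/10 mice were split into 6 sister cultures, and each culture was infected with 1 retrovirus. The 6 retroviruses were a control, DUX4, truncated DUX4, the DUX4-ERD fusion that the labels call dominant-negative, the DUX4-VP16 fusion that they call constitutively active, and DUX4c. DUX4 is a human double homeobox transcription factor linked to facioscapulohumeral muscular dystrophy, and DUX4c is a relative with near-identical homeodomains. RNA was taken after 20 h and each of the 18 cultures was read on 1 array, so each construct had 3 arrays, 1 per mouse. Arrays have no read depth, and their number limits the precision: the median SE of a log2 change was 0.11. Each change below is a log2 difference with its SE from the limma fit, and n = 3 mice for each construct throughout.

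**Figure D1:**
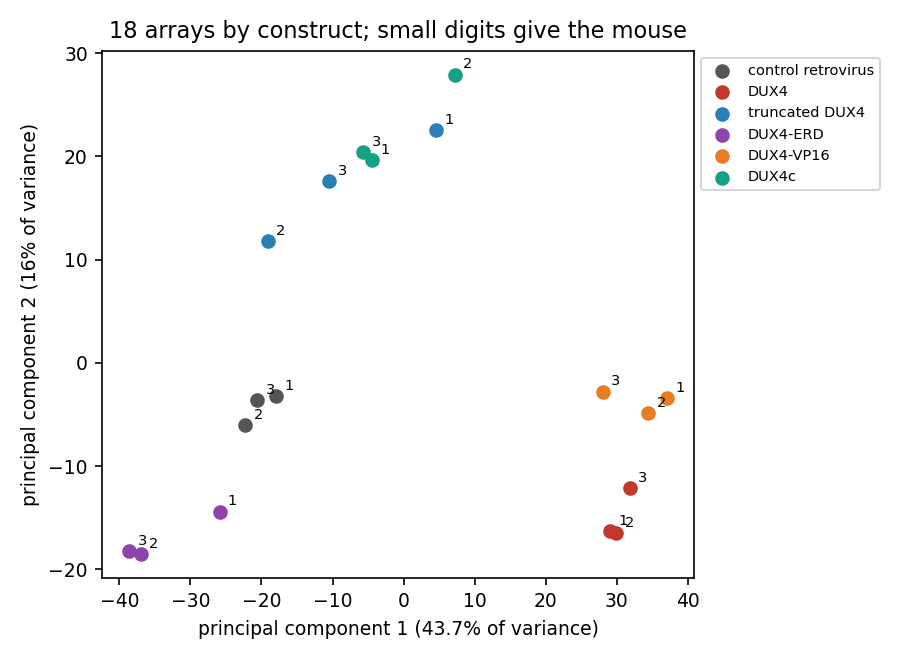
Principal components of 19938 genes, with component 1 (43.7% of the variance) on the x axis and component 2 (16%) on the y axis; each point is 1 array, coloured by construct, with its mouse as a digit. DUX4 and DUX4-VP16 arrays lay at component 1 scores of 28 to 37.1, control arrays at -22.3 to -18 and DUX4-ERD arrays at -38.6 to -25.9.

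Whether the constructs changed expression at all was asked of all 18 arrays together, and 7116 of 19938 genes differed from control with at least 1 construct by limma's moderated F test. Leaving out mouse 3 lowered that number to 3617. Arrays of a construct differed from each other by a median SD over genes of 0.098 for control, 0.115 for DUX4, 0.117 for DUX4-VP16, 0.13 for DUX4-ERD, 0.138 for DUX4c and 0.191 for truncated DUX4. The limma fit gives each gene 1 spread shared by all constructs, so the SEs below do not show these differences.

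**Figure D2:**
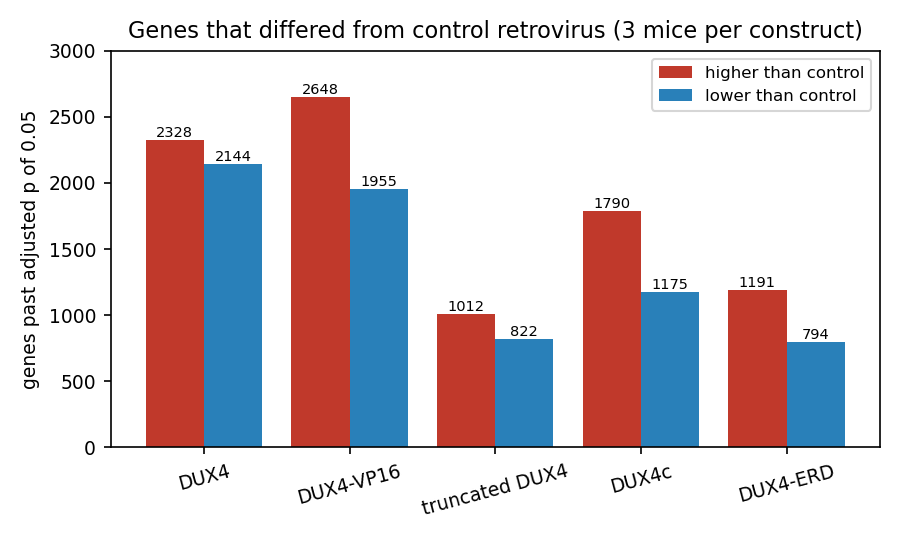
Number of genes past an adjusted p of 0.05 in each construct against control (y axis, from 0), with higher and lower genes as separate bars and 3 mice per construct. DUX4 and DUX4-VP16 had 478 and 468 genes at least 2-fold higher, and truncated DUX4 had 74.

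DUX4 against control asked what the full-length factor changes in muscle precursors. By estimate the largest rise was of Rhag (probe set 10445192), a glycoprotein of the red cell membrane. It was 56-fold higher, a log2 change of 5.81 ± 0.29 (limma adjusted p = 4.21e-09), from a mean log2 signal of 6.26 to 12.07. Olfactory and vomeronasal receptor genes had a mean signal of 6.35, so Rhag was dim in control and its fold may be understated. Dcstamp (probe set 10423894), which osteoclast precursors need in order to fuse, rose as much within the SE, 55.2-fold (5.79 ± 0.14). Lgr5, an R-spondin receptor of epithelial stem cells, rose by 4.15 ± 0.15, Tph1, an enzyme of serotonin synthesis, by 4.10 ± 0.16, P2rx3, an ATP-gated channel of sensory neurons, by 3.95 ± 0.11, and Angpt2, a ligand of the vascular receptor Tie2, by 3.95 ± 0.13. The falls were smaller, and the lowest change of any gene was -2.081. Among the falls, the tight junction gene Cldn4 changed by -1.23 ± 0.07 and the R-spondin receptor Lgr6 by -1.21 ± 0.09. The transcription factor Ets2 changed by -1.13 ± 0.10 and Pdk4, a kinase that restrains pyruvate oxidation, by -1.11 ± 0.08. Each of these genes moved the same way in 3 of 3 mice, which was a condition for naming it.

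Muscle genes fell with DUX4. Of 75 measured genes of myogenic differentiation 42 fell, 0 rose and 33 were not called (46 fell and 1 rose adjusted over the list alone), among them the atrophy ubiquitin ligase Fbxo32 (-0.94 ± 0.09), the muscle glycogen phosphorylase Pygm (-0.64 ± 0.10) and Arpp21 (-0.62 ± 0.09). The list ranked below other genes by camera (adjusted p = 3.69e-10), and adjusted p = 0.85 with an estimated correlation. Myod1, the regulator that commits cells to muscle, fell by 0.48 ± 0.06, whereas its relative Myf5 was not called (0.08 ± 0.11). Myog, which drives terminal differentiation, changed by -0.35 ± 0.10 and lost its call without any 1 of the 3 mice, without control array 1 or 2 and without DUX4 array 2. Pax7, the satellite cell factor, rose by 0.30 ± 0.07, a call that ended without mouse 1 or mouse 3, and Ctnnb1, which encodes beta-catenin, rose by 0.41 ± 0.06.

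Genes of growth and DNA replication also fell with DUX4, and those of cholesterol synthesis rose. Of 53 genes of ribosome biogenesis 32 fell, 0 rose and 21 were not called (36 fell over the list alone), including the growth regulator Myc (-0.76 ± 0.09) and the nucleolar genes Gnl3 (-0.57 ± 0.09) and Nop58 (-0.54 ± 0.09). Camera placed the list lower at adjusted p = 8.52e-10, against adjusted p = 0.747 with an estimated correlation. Of 54 genes of S phase 22 fell, 1 rose and 31 were not called (25 fell and 1 rose adjusted over the list alone), among them cyclin gene Ccne1 (-0.56 ± 0.07) and the licensing factor Cdc6 (-0.49 ± 0.09). Camera gave adjusted p = 0.000206 for that list, and adjusted p = 0.971 with an estimated correlation. Of 29 genes of cholesterol synthesis 16 rose, 3 fell and 10 were not called (16 rose and 4 fell over the list alone), with the isoprenoid isomerase Idi1 at 1.85 ± 0.13 and the sterol demethylase Cyp51 at 1.29 ± 0.14. Its camera adjusted p = 0.000114 became adjusted p = 0.85 with an estimated correlation.

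Further lists were called with DUX4, some of them not under every setting, and the cleavage-stage list was not called. Of 12 markers of smooth muscle and pericytes 6 fell and 6 were not called (6 fell over the list alone), including Notch3 (-0.87 ± 0.10) and Rgs5 (-0.83 ± 0.10), with a camera adjusted p = 0.000666 and adjusted p = 0.344 with an estimated correlation. Of 34 satellite cell and progenitor genes 16 fell, 7 rose and 11 were not called (16 and 7 over the list alone), with the Notch ligand Dll1 at -0.89 ± 0.07 and the cofactor Eya1 at 2.25 ± 0.09. That list was lower at adjusted p = 0.0415 (0.912 as adjusted p with an estimated correlation), a call that ended without mouse 1 (adjusted p = 0.061), mouse 2 (0.0929) or mouse 3 (0.0817), without the block (0.102) and after centring (0.0606). Of 37 proteasome genes 6 rose, 0 fell and 31 were not called (6 rose over the list alone), at adjusted p = 0.0346, which became adjusted p = 0.981 with an estimated correlation. That call ended without mouse 3 (0.254), without the block (0.0645), without genes below the first quartile of mean signal (0.147), after centring (0.108) and after quantile normalization (0.145). Cleavage-stage embryo genes, the kind that DUX4 switches on in human cells, were not called as a list: of 30 measured members 3 rose, 1 fell and 26 were not called (1 rose and 0 fell over the list alone), with adjusted p = 0.564. Only 30 of the list's 65 symbols were measured, so the result covers only that part. The Zscan4 copies of that stage shared their probe sets with other genes and were not in the gene table. Its member Tmem92 rose by 3.66 ± 0.21.

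The limma test called 4472 of 19938 genes with DUX4 (22.4%), 2328 higher and 2144 lower, of which 4463 moved the same way in 3 of 3 mice. At least 2-fold changes were mostly rises, 478 against 29 falls. The balance of higher and lower genes turned with the setting: 1968 genes were higher and 3075 lower when each array was centred on its median, and 2589 and 3389 after quantile normalization. It was 1912 and 2416 with the median of olfactory receptor genes as a covariate, 2745 and 3205 without the 4 arrays with the lowest first quartile, and 2395 and 2953 with only the 6 arrays of both groups. Leaving out mouse 3 lowered the number called to 1960.

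**Figure D3:**
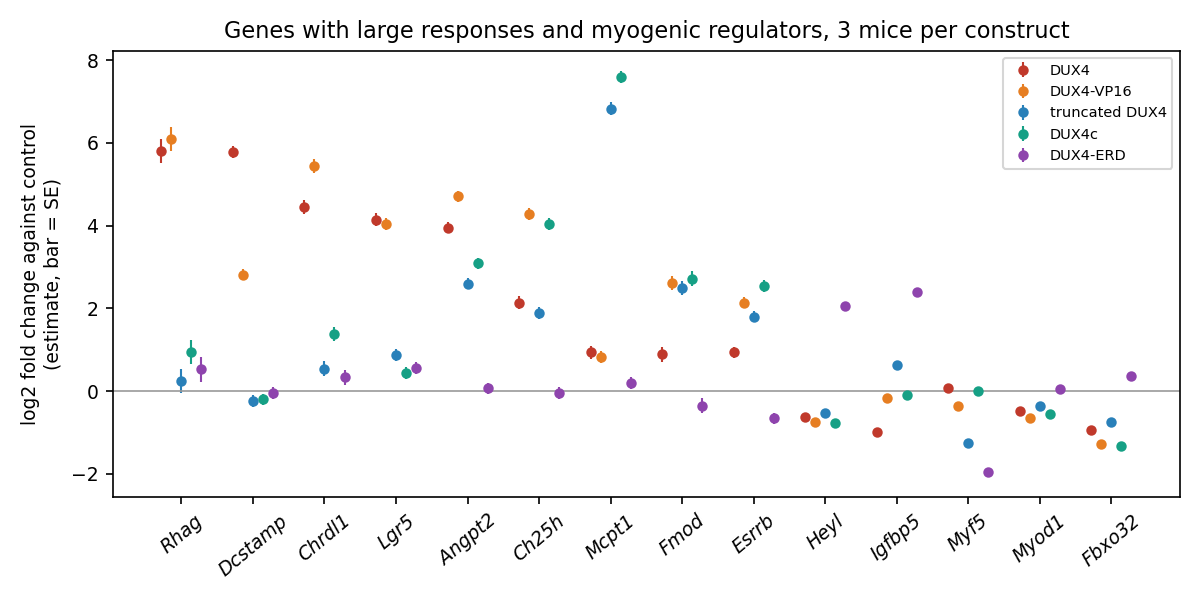
Log2 change against control (y axis) of 14 genes in 5 constructs, with points for the limma estimate and bars for its SE over 3 mice. Rhag reached 5.81 with DUX4 and 6.10 with DUX4-VP16, Mcpt1 reached 6.83 with truncated DUX4 and 7.59 with DUX4c, and Heyl was higher with DUX4-ERD and lower with the other 4.

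DUX4-VP16 carries a viral activation domain, and its comparison with control asked what a constitutively active form changes. Rhag was again the largest rise, 68.6-fold or 6.10 ± 0.29 (limma adjusted p = 2.63e-09), followed by Chrdl1 (probe set 10607124), a secreted BMP antagonist, at 5.44 ± 0.17. Angpt2 rose by 4.71 ± 0.13, Ch25h, which makes an oxysterol, by 4.28 ± 0.15, the interferon-induced Oasl2 by 4.07 ± 0.14, Lgr5 by 4.04 ± 0.15 and the embryonic transcription factor Osr2 by 4.03 ± 0.09. Cldn4 fell by 1.72 ± 0.07, Lgr6 by 1.66 ± 0.09, Pdk4 by 1.47 ± 0.08 and Dll1 by 1.46 ± 0.07. All of these moved the same way in 3 of 3 mice, as the naming rule required.

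With DUX4-VP16, 51 of 75 myogenic differentiation genes fell, 3 rose and 21 were not called (53 and 3 over the list alone). Fbxo32 changed by -1.28 ± 0.09, the actin-binding Xirp1 by -0.96 ± 0.09 and myoglobin, Mb, by -0.78 ± 0.10, while Mstn, the inhibitor of muscle growth, rose by 1.46 ± 0.19. Camera gave adjusted p = 2.62e-11, and adjusted p = 0.818 with an estimated correlation. Myod1 fell by 0.65 ± 0.06. Of 29 cholesterol synthesis genes 22 rose, 2 fell and 5 were not called (24 and 2 over the list alone), with Idi1 at 1.92 ± 0.13, Cyp51 at 1.90 ± 0.14 and Msmo1 at 1.69 ± 0.12. That list had adjusted p = 3.05e-11, and adjusted p = 0.539 with an estimated correlation. Of 53 ribosome biogenesis genes 28 fell, 1 rose and 24 were not called (33 and 1 over the list alone), among them Myc (-0.88 ± 0.09) and Dkc1 (-0.54 ± 0.09), at adjusted p = 7.83e-08, or adjusted p = 0.844 with an estimated correlation.

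Of 38 immediate early genes 17 fell with DUX4-VP16, 5 rose and 16 were not called (19 and 7 over the list alone). The phosphatase Dusp1, which switches off MAP kinases, fell by 1.27 ± 0.08 and Jun by 0.90 ± 0.08, while Dusp6 rose by 1.01 ± 0.09. The list had adjusted p = 0.00515, and adjusted p = 0.885 with an estimated correlation. In S phase genes 18 of 54 fell, 3 rose and 33 were not called (22 and 3 over the list alone), with Ccne1 at -0.60 ± 0.07, adjusted p = 0.000721 and adjusted p = 0.971 with an estimated correlation. Of 24 replication-dependent histone genes 9 fell, 0 rose and 15 were not called (11 fell over the list alone), at adjusted p = 0.00515, or adjusted p = 0.912 with an estimated correlation, and the call ended without mouse 2 (adjusted p = 0.083). Of 12 smooth muscle and pericyte markers 6 fell and 6 were not called (6 over the list alone), with Notch3 at -1.10 ± 0.10, adjusted p = 0.00082 and adjusted p = 0.344 with an estimated correlation. Of 37 proteasome genes 7 rose, 2 fell and 28 were not called (7 and 2 over the list alone), at adjusted p = 0.00493, or adjusted p = 0.971 with an estimated correlation, and the call ended without dim genes, those below the first quartile of mean signal (0.0551), and after quantile normalization (0.123). Of 23 macrophage and leukocyte markers 4 fell, 0 rose and 19 were not called (4 fell over the list alone), at adjusted p = 0.0426, or adjusted p = 0.93 with an estimated correlation, and the call ended without dim genes (0.135), after centring (0.0542) and after quantile normalization (0.418).

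With DUX4-VP16 limma called 4603 genes (23.1%), 2648 higher and 1955 lower, of which 4591 moved the same way in 3 of 3 mice. The balance turned to 2251 higher and 2611 lower after centring and to 2642 and 3163 after quantile normalization. At least 2-fold changes were 468 rises and 73 falls. The number called was 3033 without mouse 1 and 2164 without mouse 3.

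DUX4 and DUX4-VP16 changed many of the same genes. The number called higher with both was 1864, against 309 for independent sets of those sizes, and the number called lower with both was 1466, against 210. Opposite calls were made for 17 genes, among them Fgf7 and Vcam1, which were chosen after their values were seen, and numbered 6, 4 and 0 without mouse 1, 2 or 3. Of the 478 genes that DUX4 raised at least 2-fold, 448 (93.7%) were called higher with DUX4-VP16 and 0 lower. The number called the same way in both was 3330, and 2199 without mouse 1 and 1437 without mouse 3. Across genes, which are not independent replicates, the changes had a covariance of 0.143, against 0.00822 from the shared controls alone.

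DUX4-VP16 against DUX4 tested the difference between both directly. S1pr1, a receptor for sphingosine-1-phosphate, was higher with the fusion by 2.54 ± 0.09, Ch25h by 2.14 ± 0.15 and Sfrp2, a secreted Wnt modulator, by 2.14 ± 0.17. Necab1, a neuronal calcium-binding protein, was lower, at -3.63 ± 0.12, as were Dcstamp, at -2.97 ± 0.14, and Aqp4, a water channel of astrocytes and muscle, at -2.69 ± 0.13. Of 29 cholesterol synthesis genes 10 were higher with the fusion and 0 lower (15 and 0 over the list alone), with camera adjusted p = 6.06e-11 and adjusted p = 0.584 with an estimated correlation. Of 38 immediate early genes 7 were lower and 2 higher (9 and 2 over the list alone), with adjusted p = 0.000386 and adjusted p = 0.917 with an estimated correlation. Of 24 histone genes limma called 0 singly (3 lower and 0 higher at an unadjusted p under 0.05) although the list ranked lower (adjusted p = 0.0177, and adjusted p = 0.991 with an estimated correlation), and neural and neural crest genes ranked lower with 3 of 44 lower and 2 higher (3 and 3 over the list alone) at adjusted p = 0.0254, or adjusted p = 0.991 with an estimated correlation.

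The limma test called 909 genes between DUX4-VP16 and DUX4, 482 higher and 427 lower with the fusion, all 909 with 1 sign in 3 of 3 mice. The balance turned with all probe sets (379 higher and 400 lower), after quantile normalization (711 and 719) and without mouse 1 (183 and 214), mouse 2 (187 and 235) or mouse 3 (96 and 114). It also turned without DUX4 array 1 (284 and 322) or 2 (273 and 279) and without DUX4-VP16 array 1 (296 and 304) or 2 (255 and 281). The number was 397 without mouse 1, 422 without mouse 2 and 210 without mouse 3. It was 600, 536 and 561 without DUX4-VP16 array 1, 2 or 3 and 552 without DUX4 array 2.

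Truncated DUX4 against control asked what is left when part of the factor is missing. Mcpt1 (probe set 10415431), a protease of mucosal mast cells, was 114-fold higher, a change of 6.83 ± 0.15 (limma adjusted p = 3.58e-12). Angpt2 was 6.04-fold higher (SE of the log2 change 0.13). Fmod, a small proteoglycan of tendon and matrix, rose by 2.49 ± 0.18, the secreted protease Htra1 by 2.33 ± 0.12, the growth factor Fgf7 by 1.90 ± 0.15 and the chemokine Ccl17 by 1.83 ± 0.10. Cmah, which makes a sialic acid, fell by 1.64 ± 0.10, Myf5 by 1.25 ± 0.11 and the muscle transcription factor Mef2c by 1.08 ± 0.12. These moved the same way in 3 of 3 mice, as the naming rule required.

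With truncated DUX4, 51 of 75 myogenic differentiation genes fell, 0 rose and 24 were not called (60 fell over the list alone). The sarcomere gene Myom2 changed by -1.05 ± 0.09, the fusion peptide gene Mymx by -0.83 ± 0.08, the acetylcholine receptor subunit Chrnd by -0.82 ± 0.08 and Myog by -0.75 ± 0.10. Camera gave adjusted p = 1.29e-35, and adjusted p = 0.344 with an estimated correlation. Myod1 fell by 0.37 ± 0.06, a call that ended without mouse 3. Of 34 satellite cell genes 11 fell, 3 rose and 20 were not called (13 and 4 over the list alone), with the receptor Fgfr4 at -0.83 ± 0.08, adjusted p = 0.000666 and adjusted p = 0.714 with an estimated correlation. Of 49 genes of glutathione and oxidative stress 13 rose, 1 fell and 35 were not called (16 and 1 over the list alone), including the cystine transporter Slc7a11 (1.15 ± 0.10), Srxn1 (1.11 ± 0.09) and Gclc (0.68 ± 0.08), while Osgin1 fell by 0.79 ± 0.09. That list had adjusted p = 1.49e-06, and adjusted p = 0.539 with an estimated correlation. Of the 29 genes of the cholesterol synthesis list 11 rose, 0 fell and 18 were not called (14 rose over the list alone). Its member Scd1, a fatty acid desaturase, changed by 0.64 ± 0.07. Camera gave adjusted p = 1.39e-06 for the list, and adjusted p = 0.714 with an estimated correlation. Of 12 smooth muscle and pericyte markers 5 fell and 7 were not called (6 fell over the list alone), with adjusted p = 2.51e-05, or adjusted p = 0.26 with an estimated correlation.

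Other lists were called with truncated DUX4 although few members were. S phase genes ranked lower with 3 of 54 falling and 0 rising (3 and 0 over the list alone) at adjusted p = 0.00473, or adjusted p = 0.981 with an estimated correlation, and that call ended without mouse 2 (adjusted p = 0.354) or mouse 3 (0.0506). Unfolded protein response genes ranked lower with 8 of 45 falling and 2 rising (9 and 2 over the list alone) at adjusted p = 0.0347, or adjusted p = 0.971 with an estimated correlation, and ended without mouse 2 (0.17) or mouse 3 (0.152) and without the block (0.0529). Cytoskeletal targets of SRF ranked lower with 6 of 31 falling and 2 rising (6 and 2 over the list alone) at adjusted p = 0.0444, or adjusted p = 0.971 with an estimated correlation, and ended without mouse 2 (0.414) or mouse 3 (0.106) and without the block (0.0844). Cleavage-stage genes ranked lower with 0 of 30 called by limma (0 over the list alone, and 4 lower and 0 higher at an unadjusted p under 0.05) at adjusted p = 0.0346, or adjusted p = 0.96 with an estimated correlation, and ended without mouse 1 (0.369), without dim genes (0.188), after centring (0.0665) and after quantile normalization (0.0769). Hypoxia genes ranked higher with 3 of 36 rising and 2 falling (3 and 2 over the list alone) at adjusted p = 0.0426, or adjusted p = 0.96 with an estimated correlation, and ended without mouse 1 (0.22) or mouse 3 (0.0561), without dim genes (0.134), after centring (0.0663) and after quantile normalization (0.0838). Oxidative phosphorylation genes ranked higher with 0 of 65 called by limma (0 over the list alone, and 9 higher and 1 lower at an unadjusted p under 0.05) at adjusted p = 0.0426, or adjusted p = 0.981 with an estimated correlation, and ended without mouse 1 (0.116) or mouse 3 (0.425), without the block (0.0922), without dim genes (0.17), after centring (0.147) and after quantile normalization (0.148).

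The limma test called 1834 genes with truncated DUX4 (9.2%), 1012 higher and 822 lower, of which 1833 moved the same way in 3 of 3 mice, with 74 rises and 16 falls of at least 2-fold. The balance turned to 833 higher and 1058 lower after centring, 1405 and 1412 after quantile normalization, 757 and 1121 with the receptor covariate and 727 and 1009 without the 4 arrays with the lowest first quartile. It also turned without mouse 1 (355 and 566), truncated DUX4 array 1 (623 and 894) or control array 1 (645 and 648). The number was 921 without mouse 1, 337 without mouse 3 and 1201 without control array 2. It was 411 when only the 6 arrays of both groups were fitted.

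DUX4c against control asked what the related factor changes. Mcpt1 was 193-fold higher, a change of 7.59 ± 0.15 (limma adjusted p = 8.5e-13), and Ch25h 16.4-fold higher (4.03 ± 0.15). Angpt2 rose by 3.09 ± 0.13, Fmod by 2.72 ± 0.18, the orphan nuclear receptor Esrrb by 2.54 ± 0.14 and Ccl17 by 2.33 ± 0.10. Cmah fell by 1.62 ± 0.10, Fbxo32 by 1.33 ± 0.09, Popdc2, a membrane protein of heart and muscle, by 1.30 ± 0.09 and the chemokine Cxcl12 by 1.19 ± 0.10. All moved the same way in 3 of 3 mice, as the naming rule required.

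With DUX4c, 57 of 75 myogenic differentiation genes fell, 0 rose and 18 were not called (62 fell over the list alone), including Myom2 (-1.18 ± 0.09), the calcium channel subunit Cacng1 (-1.08 ± 0.13) and Mef2c (-1.07 ± 0.12). Camera gave adjusted p = 9.98e-39, and adjusted p = 0.344 with an estimated correlation. Myod1 fell by 0.55 ± 0.06 and Myog by 0.79 ± 0.10, while Myf5 was not called (-0.01 ± 0.11). Of 69 mitosis genes 21 rose, 1 fell and 47 were not called (30 and 1 over the list alone), with the spindle genes Ckap2l at 0.68 ± 0.07 and Nusap1 at 0.62 ± 0.08 and the phosphatase Cdc25b at -0.66 ± 0.08. That list had adjusted p = 4.23e-09, and adjusted p = 0.852 with an estimated correlation. The proliferation marker Mki67 rose by 0.41 ± 0.08, a call that ended without mouse 3. Of 29 cholesterol synthesis genes 17 rose, 1 fell and 11 were not called (23 and 1 over the list alone), with Idi1 at 1.10 ± 0.13 and Scd1 at 0.74 ± 0.07, adjusted p = 1.22e-10 and adjusted p = 0.539 with an estimated correlation.

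Of 49 glutathione and oxidative stress genes 13 rose with DUX4c, 1 fell and 35 were not called (18 and 3 over the list alone), with Slc7a11 at 0.91 ± 0.10 and the metallothionein Mt2 at 0.55 ± 0.07, adjusted p = 0.000563 and adjusted p = 0.747 with an estimated correlation. Of 34 satellite cell genes 12 fell, 5 rose and 17 were not called (13 and 5 over the list alone), with Fgfr4 at -0.97 ± 0.08, adjusted p = 0.000206 and adjusted p = 0.714 with an estimated correlation. Of 12 smooth muscle and pericyte markers 7 fell, 1 rose and 4 were not called (8 and 1 over the list alone), with the proteoglycan Cspg4 at -0.82 ± 0.09 and Tagln at -0.78 ± 0.09, adjusted p = 2.95e-05 and adjusted p = 0.26 with an estimated correlation. Of 65 oxidative phosphorylation genes 8 rose, 0 fell and 57 were not called (4 rose over the list alone), at adjusted p = 0.00012, or adjusted p = 0.885 with an estimated correlation. Ribosomal protein genes ranked higher with 1 of 53 rising and 0 falling (0 over the list alone) at adjusted p = 0.0132, or adjusted p = 0.971 with an estimated correlation, and that call ended without mouse 2 (adjusted p = 0.127), without the block (0.0562), without dim genes (0.111), after centring (0.0886) and after quantile normalization (0.0951).

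With DUX4c limma called 2965 genes (14.9%), 1790 higher and 1175 lower, of which 2962 moved the same way in 3 of 3 mice, with 159 rises and 41 falls of at least 2-fold. The balance turned to 1335 higher and 1490 lower after centring, 815 and 921 without mouse 2, and 1263 and 1267 without DUX4c array 2. The number was 1736 without mouse 2, 969 without mouse 3 and 1791 when only the 6 arrays of both groups were fitted.

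Truncated DUX4 and DUX4c were set side by side only after their values were seen. The number called higher with both was 866, against 90.9 for independent sets, and the number called lower with both was 702, against 48.4. The number called the same way in both, 1568, was 814, 893 and 298 without mouse 1, 2 or 3. Opposite calls numbered at most 1 as reported and under each setting tried. Of the 74 genes that truncated DUX4 raised at least 2-fold, 72 were called higher with DUX4c, among them Mcpt1, Angpt2, Fmod and Htra1. Across genes the covariance was 0.0586, against 0.00824 from the shared controls.

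The overlap of DUX4 with DUX4c held 835 genes called higher with both, against 209 for independent sets, and lower with both 713, against 126. Opposite calls were made for 202 genes, for 100, 101 and 38 without mouse 1, 2 or 3, for 131 without the block and for 363 after quantile normalization. As reported they were fewer than for independent sets. Higher with DUX4 and lower with DUX4c were 87, against 137, and the reverse 115, against 192. Ret, a receptor of glial-derived growth factors, changed by 1.79 ± 0.07 with DUX4 and -0.92 ± 0.07 with DUX4c, and Greb1, an estrogen-responsive gene, by -0.77 ± 0.13 and 1.66 ± 0.13. Slc7a11 changed by -0.93 ± 0.10 with DUX4 and 0.91 ± 0.10 with DUX4c. Of the 478 genes that DUX4 raised at least 2-fold, 231 were called higher with DUX4c and 16 lower. The covariance across genes was 0.0567, against 0.00821 from the shared controls. The number called the same way in both, 1548, was 994, 877 and 454 without mouse 1, 2 or 3.

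DUX4 against DUX4c tested that difference directly. Dcstamp was 63.4-fold higher with DUX4 (5.99 ± 0.14), Rhag 29.2-fold higher (4.87 ± 0.29) and Necab1 20.3-fold higher (4.35 ± 0.12). Mcpt1 was lower, at -6.66 ± 0.15, as were Fgf7, at -2.93 ± 0.15, and P3h2, a collagen prolyl hydroxylase, at -2.83 ± 0.08. Of 75 myogenic differentiation genes 36 were higher with DUX4 and 2 lower (48 and 3 over the list alone), with adjusted p = 4.16e-12 and adjusted p = 0.917 with an estimated correlation. Of 53 ribosome biogenesis genes 33 were lower and 0 higher (39 and 0 over the list alone), with adjusted p = 4.16e-12 and adjusted p = 0.756 with an estimated correlation. Of 69 mitosis genes 32 were lower and 1 higher (41 and 1 over the list alone), with adjusted p = 6.65e-09 and adjusted p = 0.991 with an estimated correlation. Against control that list was not called by camera with DUX4 (adjusted p = 0.649), where 4 genes rose, 8 fell and 57 were not called. With DUX4c 21 of them rose against control. Of 54 S phase genes 26 were lower and 1 higher (33 and 1 over the list alone), with adjusted p = 3.33e-07 and adjusted p = 0.991 with an estimated correlation. Camera called 3 of 34 lists higher and 6 lower with DUX4, only some of them given here, and 0 held with an estimated correlation. The limma test called 3984 genes, 1948 higher and 2036 lower with DUX4, 3969 of them with 1 sign in 3 of 3 mice. The balance turned without mouse 1 (1398 higher and 1341 lower), mouse 2 (1747 and 1092) or mouse 3 (932 and 752), and without DUX4 array 1 (1831 and 1597), DUX4 array 2 (1536 and 1373) or DUX4c array 2 (2198 and 1686). It also turned without the block (1672 and 1621), with all probe sets (2150 and 2147), without the 4 arrays with the lowest first quartile (2254 and 1928) and with only 6 arrays (1317 and 921). The number was 1684 without mouse 3 and 2238 when only the 6 arrays of both groups were fitted.

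DUX4 against truncated DUX4 gave 4042 called genes, 2128 higher and 1914 lower with DUX4, 4012 of them with 1 sign in 3 of 3 mice. The balance turned to 2001 higher and 2238 lower after centring, 2426 and 2921 after quantile normalization and 2348 and 2462 with the receptor covariate, and to 1508 and 1540 without mouse 2 and 1788 and 2302 without truncated DUX4 array 2. Dcstamp was 65.4-fold higher with DUX4 (6.03 ± 0.14), Rhag 47.3-fold higher (5.56 ± 0.29) and the cadherin Cdh20 20.6-fold higher (4.36 ± 0.14). Mcpt1 was lower, at -5.90 ± 0.15, as were Fgf7, at -2.53 ± 0.15, and Slc7a11, at -2.08 ± 0.10. Of 53 ribosome biogenesis genes 39 were lower with DUX4 and 0 higher (43 and 0 over the list alone), with adjusted p = 3.01e-13 and adjusted p = 0.675 with an estimated correlation. Of 75 myogenic differentiation genes 19 were higher and 3 lower (21 and 3 over the list alone), with adjusted p = 0.000513 and adjusted p = 0.991 with an estimated correlation. Camera called 1 of 34 lists higher and 4 lower with DUX4, only some of them given here, and 0 held with an estimated correlation. The number of genes called was 1694 without mouse 3 and 1745 when only the 6 arrays of both groups were fitted.

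DUX4-ERD carries a repressor domain, and its comparison with control asked what a dominant-negative form changes in cells that were given no DUX4. Idi2 (probe set 10403420), a relative of the isoprenoid isomerase Idi1, was 7.05-fold higher, a change of 2.82 ± 0.23 (limma adjusted p = 2.09e-06). Ngfr, the neurotrophin receptor, rose by 2.44 ± 0.10, Igfbp5, a growth factor-binding protein of differentiating muscle, by 2.40 ± 0.09, the vitamin D receptor Vdr by 2.37 ± 0.13, the cell cycle inhibitor Cdkn1c by 2.07 ± 0.08 and the Notch target Heyl by 2.05 ± 0.07. Dynap fell by 2.24 ± 0.10, Myf5 by 1.96 ± 0.11, the caveola component Cavin2 by 1.93 ± 0.14 and Ahr, the dioxin receptor, by 1.61 ± 0.10. All moved the same way in 3 of 3 mice, as the naming rule required.

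Notch pathway genes rose with DUX4-ERD: 11 of 29 rose, 2 fell and 16 were not called (11 and 2 over the list alone), with Hes1 at 1.39 ± 0.09, Notch1 at 1.10 ± 0.07 and Nrarp at 1.08 ± 0.16. Camera gave adjusted p = 0.000354, and adjusted p = 0.392 with an estimated correlation. Of 38 immediate early genes 18 rose, 4 fell and 16 were not called (20 and 7 over the list alone), with Arc at 1.44 ± 0.08, Nr4a1 at 1.20 ± 0.08, Egr3 at 1.06 ± 0.06 and Nr4a2 at -1.03 ± 0.07. That list had adjusted p = 2.69e-06, and adjusted p = 0.714 with an estimated correlation. Of 49 glutathione and oxidative stress genes 12 rose, 2 fell and 35 were not called (14 and 4 over the list alone), with heme oxygenase Hmox1 at 0.74 ± 0.09 and Mgst2 at 0.88 ± 0.13, adjusted p = 0.00204 and adjusted p = 0.84 with an estimated correlation. Oxidative phosphorylation genes ranked higher with 1 of 65 rising (0 over the list alone) at adjusted p = 0.00082, or adjusted p = 0.96 with an estimated correlation. Ribosome biogenesis genes ranked lower with 3 of 53 falling and 0 rising (3 over the list alone) at adjusted p = 8.15e-05, or adjusted p = 0.93 with an estimated correlation. S phase genes ranked lower with 4 of 54 falling and 2 rising (4 and 2 over the list alone) at adjusted p = 0.00221, or adjusted p = 0.981 with an estimated correlation, and that call ended without mouse 3 (adjusted p = 0.14).

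Myogenic differentiation genes were not called as a list with DUX4-ERD: of 75 measured 13 fell, 8 rose and 54 were not called (15 and 8 over the list alone), with a median of 0.02, a mean of -0.015 and a camera adjusted p = 0.825 in the lower direction. Mstn fell by 1.29 ± 0.19 and Klhl40, a sarcomere chaperone, rose by 0.97 ± 0.10. Myod1 (0.05 ± 0.06) and Myog (-0.16 ± 0.10) were not called. Of 34 satellite cell genes 14 rose, 6 fell and 14 were not called (16 and 8 over the list alone), with adjusted p = 0.0658. The limma test called 1985 genes (9.96%), 1191 higher and 794 lower, all 1985 with 1 sign in 3 of 3 mice, with 97 rises and 68 falls of at least 2-fold. The number was 1009, 1243 and 635 without mouse 1, 2 or 3, and 1313 without control array 1.

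DUX4-VP16 and DUX4-ERD were compared because the labels call the first constitutively active and the second dominant-negative. Opposite calls were made for 852 genes, of which 375 were higher with DUX4-VP16 and lower with DUX4-ERD (105 for independent sets) and 477 the reverse (117). The same direction was called for 307 genes, 140 higher with both (158 for independent sets) and 167 lower with both (77.9). Cavin2 changed by 2.15 ± 0.14 with DUX4-VP16 and -1.93 ± 0.14 with DUX4-ERD, the monooxygenase Fmo1 by 1.71 ± 0.11 and -1.74 ± 0.11, and Hhip, which binds hedgehog ligands, by 2.23 ± 0.14 and -1.60 ± 0.14. Mstn changed by 1.46 ± 0.19 and -1.29 ± 0.19, and the hedgehog release factor Disp2 by -1.21 ± 0.12 and 2.16 ± 0.12. Ngfr rose with both, by 0.93 ± 0.10 and 2.44 ± 0.10. Of the 468 genes that DUX4-VP16 raised at least 2-fold, 128 were called lower with DUX4-ERD and 19 higher. Across genes the covariance was -0.0115, against 0.00824 from the shared controls. Without mouse 1, 2 or 3 the opposite calls numbered 477, 499 and 228 and the calls in 1 direction 113, 159 and 45, and without the mouse as a block 181 genes were called in 1 direction.

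**Figure D4:**
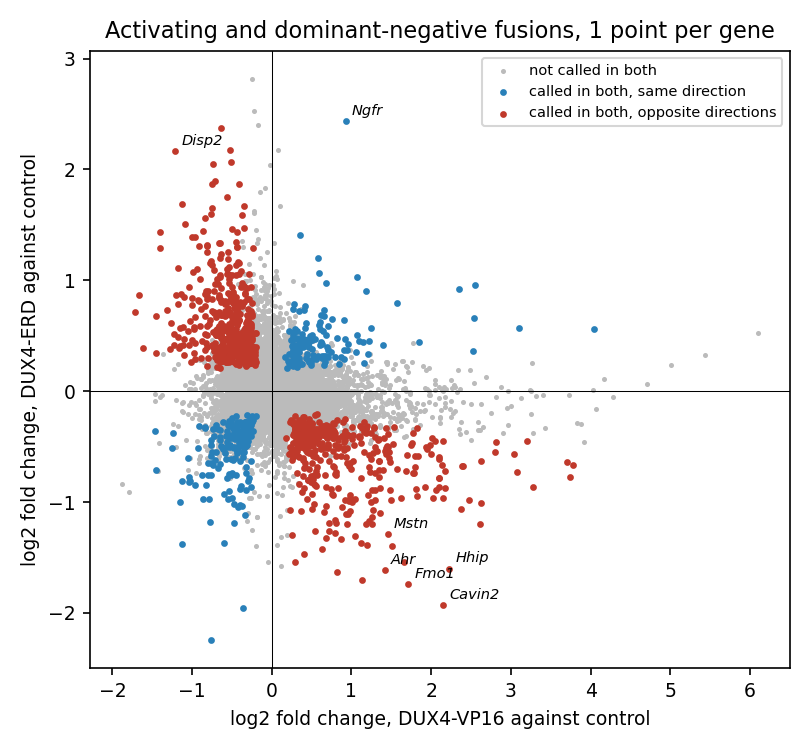
Log2 change against control with DUX4-VP16 (x axis) and with DUX4-ERD (y axis), 1 point per gene, 3 mice per construct, coloured by whether limma called the gene in both comparisons and in which directions. The 852 genes called in opposite directions lie at the upper left and lower right, and the 307 called in the same direction in the others.

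DUX4-VP16 against DUX4-ERD tested that difference directly and called 5543 genes, 3074 higher and 2469 lower with DUX4-VP16, 5536 of them with 1 sign in 3 of 3 mice. After quantile normalization the balance turned to 3102 higher and 3460 lower. Rhag was 47.8-fold higher with DUX4-VP16 (5.58 ± 0.29), Chrdl1 34.5-fold higher (5.11 ± 0.17) and Angpt2 24.9-fold higher (4.64 ± 0.13). Disp2 was lower, at -3.37 ± 0.12, as were Vdr, at -3.01 ± 0.13, and Heyl, at -2.79 ± 0.07. Of 75 myogenic differentiation genes 42 were lower with DUX4-VP16 and 8 higher (46 and 10 over the list alone), with adjusted p = 2.2e-06 and adjusted p = 0.991 with an estimated correlation. Of 38 immediate early genes 22 were lower and 6 higher (24 and 6 over the list alone), with adjusted p = 1.72e-05 and adjusted p = 0.756 with an estimated correlation. Of 29 cholesterol synthesis genes 18 were higher and 2 lower (19 and 2 over the list alone), with adjusted p = 4.18e-07 and adjusted p = 0.756 with an estimated correlation. Camera called 2 of 34 lists higher and 4 lower with DUX4-VP16, only some of them given here, and 0 held with an estimated correlation. Without mouse 3 the number of genes called was 3272.

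**Figure D5:**
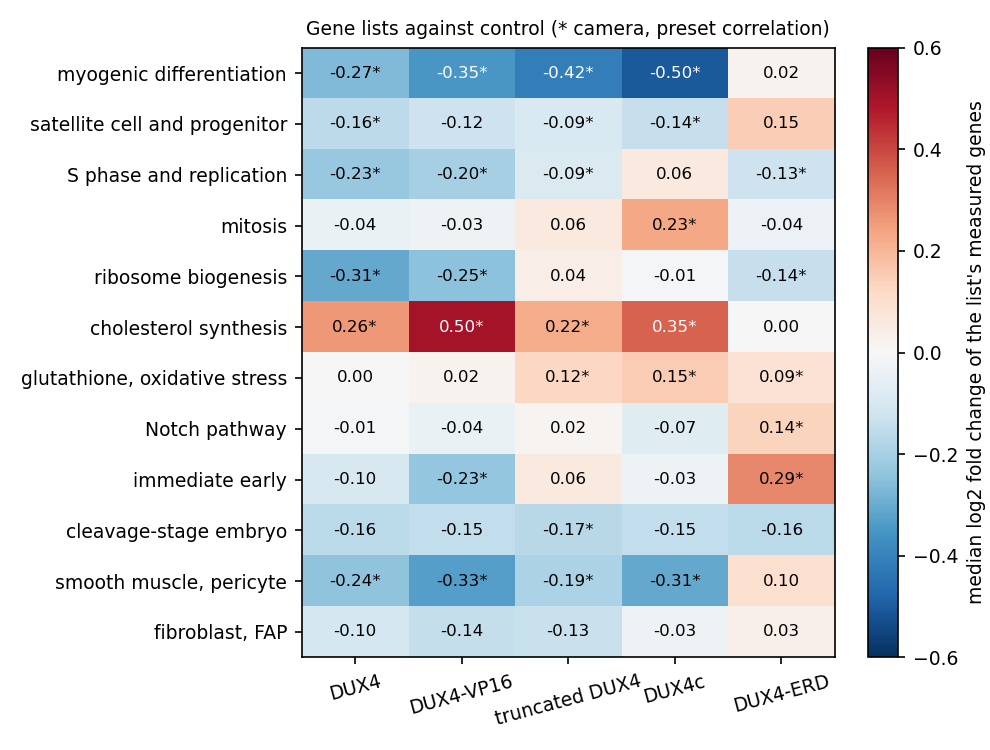
Median log2 change of 12 gene lists (y axis) in 5 constructs against control (x axis), with the colour and the printed number giving the median over each list's measured genes and an asterisk a list past an adjusted p of 0.05 by camera with a preset correlation. Myogenic differentiation had medians of -0.27 with DUX4, -0.42 with truncated DUX4, 0.02 with DUX4-ERD, -0.35 with DUX4-VP16 and -0.50 with DUX4c.

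Across the 5 constructs camera with a preset correlation called 41 of 170 list tests, and 28 of them held under each of 7 other settings. With an estimated correlation 0 of the 170 passed in camera, where 12 had an unadjusted p under 0.05, and 54 passed by limma's fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes.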

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

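The tests of a difference between mice and of a stronger response in single cultures were chosen after the result was seen, and the test of response was widened from 3 to 5 constructs after its values were known.

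Probe sets that the comparisons left out carried signal that differed from control cultures, tested with limma over all 35556 probe sets together. They drew attention because this signal lies outside the gene table. Of the 1621 probe sets with several gene symbols, 44 were higher than control with DUX4, 18 with truncated DUX4, 19 with DUX4-ERD, 50 with DUX4-VP16 and 31 with DUX4c, and 133, 13, 27, 120 and 18 were lower. Of the 12146 probe sets without a gene symbol, 289 were higher with DUX4, 75 with truncated DUX4, 116 with DUX4-ERD, 338 with DUX4-VP16 and 151 with DUX4c, and 624, 68, 79, 452 and 172 were lower. As a share this was 2.38% higher with DUX4 among probe sets without a symbol, against 10.6% among those with 1 symbol. The largest rise among probe sets without a symbol was 3.43 on the log2 scale, with DUX4, and among those with several symbols 5.23, with DUX4c. No explanation was tested for probe sets without a symbol. No test for a single array that lies apart was run within the groups of 3.

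Arrays of the same construct deviated from each other along 1 axis shared by several constructs, which held 48.5% of the sum of squares within groups, with the largest scores for truncated DUX4 mouse 1 (-30.1) and mouse 2 (27.1), DUX4-ERD mouse 1 (-20.2) and DUX4c mouse 2 (-19.5). A stronger or weaker response to the construct in single cultures may contribute and stays open: across 18744 genes, which are not independent replicates, the axis loading correlated with the effects of DUX4, truncated DUX4, DUX4-ERD, DUX4-VP16 and DUX4c at r = -0.191, -0.131, 0.044, -0.303 and -0.186, and on the principal components truncated DUX4 mouse 1 (4.6 and 22.5) lay farther from the control arrays than mouse 2 (-19.1 and 11.8). An earlier form of that test pointed the other way, with r = -0.259 between the deviation of truncated DUX4 mouse 1 and the DUX4c effect over the 200 genes that DUX4c changed at least 2-fold. An array-wide difference in signal at dim probe sets may contribute as well: over 18 arrays the axis followed the median of 1194 receptor genes at Pearson r = 0.632 (permutation p = 0.006), Spearman rho = 0.567 (permutation p = 0.02) and r = 0.475 without the 2 arrays farthest from the median. The permutations shuffled all 18 values, although these were centred within constructs and are not freely exchangeable, so the p-values may be too small. The first quartile over the axis genes deviated from its construct's mean by -0.17 and 0.18 in truncated DUX4 mouse 1 and 2. It deviated by -0.14 in DUX4-ERD mouse 1 and -0.13 in DUX4c mouse 2, each with the sign of its score. The third quartile over genes went the other way in truncated DUX4, 10.08 in mouse 1 and 9.798 in mouse 2. No bounds were set for the quartiles, and the first comes from the genes that make the axis. Mouse held a share of 0.304 of the sum of squares on the axis. The tests of response, receptor median and mouse each gave a value between the bounds set for and against its explanation. A difference in response, between arrays or between mice therefore cannot be told apart here.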

How the results depend on the processing

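The limits of these results lie in 3 mice and in dim signal: without detection calls, changes of dim genes are understated, and a change of 0.5 on the log2 scale was recovered in 54% to 64% of simulated genes. The receptor covariate, the omission of the 4 arrays with the lowest first quartile, the list medians after quantile normalization, the list calls under 7 settings, the overlap of truncated DUX4 with DUX4c and the opposite calls other than those of DUX4-VP16 and DUX4-ERD were chosen after seeing the data. The random block, the trended prior, the dim-gene filter, all probe sets, the centring, the receptor covariate and the omission of 4 arrays left each of the 9 counts of called genes, that of the F test and those of genes called the same way by a pair of constructs within 1.5 times the reported value. Opposite calls of DUX4 and DUX4-VP16, 17 as reported, numbered 10 with the random block and 26 without the 4 arrays. The median change of all genes with DUX4 was -0.051 as reported, -0.112 after centring and -0.035 after quantile normalization. Whether more genes were higher or lower turned in at least 1 setting in each of the 9 comparisons except DUX4-ERD against control. Dropping the mouse as a block, which ignores the pairing of sister cultures, lowered the genes called in the same direction by DUX4-VP16 and DUX4-ERD from 307 to 181, the opposite calls of DUX4 and DUX4c from 202 to 131 and those of DUX4 and DUX4-VP16 to 6.

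With only the 6 arrays of both groups, whose spread is then estimated from those groups alone, counts moved both ways: 5348 genes were called with DUX4, 5238 with DUX4-VP16 and 6013 for DUX4-VP16 against DUX4-ERD, whereas 411 genes were called with truncated DUX4, 1791 with DUX4c, 2238 for DUX4 against DUX4c and 1745 for DUX4 against truncated DUX4, and the cause was not tested. Quantile normalization called 2817 genes with truncated DUX4, 1430 for DUX4-VP16 against DUX4, 585 in the same and 1289 in opposite directions by DUX4-VP16 and DUX4-ERD, 363 in opposite directions by DUX4 and DUX4c and 33 by DUX4 and DUX4-VP16, and the cause was not tested. Camera with an estimated correlation called 0 of the 170 lists, where 12 had an unadjusted p under 0.05, against 41 at the preset correlation and 54 by fry. Leaving out 1 mouse or 1 array, which leaves fewer arrays, gave 1960 to 3800 genes with DUX4, 337 to 2346 with truncated DUX4, 635 to 1529 with DUX4-ERD, 2164 to 3840 with DUX4-VP16 and 969 to 3097 with DUX4c. It gave 1684 to 3884 for DUX4 against DUX4c, 1694 to 4090 for DUX4 against truncated DUX4, 210 to 648 for DUX4-VP16 against DUX4 and 3272 to 5013 for DUX4-VP16 against DUX4-ERD. Without 1 mouse the F test called 3617 to 5504 genes, and genes called the same way numbered 1437 to 2333 with DUX4 and DUX4-VP16, 454 to 994 with DUX4 and DUX4c, 298 to 893 with truncated DUX4 and DUX4c, and 45 to 159 with DUX4-VP16 and DUX4-ERD, where opposite calls numbered 228 to 499. Those of DUX4 and DUX4c numbered 38 to 101 and those of DUX4 and DUX4-VP16 0 to 6. The lowest of each of these ranges was without mouse 3. Opposite calls of truncated DUX4 and DUX4c numbered 1 with the trended prior, without dim genes and after quantile normalization. Called lists numbered 39 to 46, with the highest without mouse 2.

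No call of a named gene turned direction in limma under these settings. With all probe sets 645 of their calls were kept and 53 ended, and the numbers kept were 682 centred, 680 quantile-normalized, 686 with the trended prior, 680 with the random block, 630 without the block, 655 with the receptor covariate, 612 with 6 arrays, 662 without the 4 arrays and 481 in every omission of 1 mouse or array. Of 41 list calls 28 held under each of 7 settings and 0 turned. The others, given with their comparisons, ended in at least 1 of these settings.

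Key genes that were not called and lay near 0 changed sign. After centring Actb was -0.00481 with DUX4, -0.0293 with truncated DUX4, -0.0373 with DUX4-VP16 and -0.00787 with DUX4c, Ctnnb1 -0.0138 with truncated DUX4 and -0.00636 with DUX4c, Pax3 -0.0355 and Mki67 -0.00872 with DUX4-ERD, and Pax7 -0.0282 with DUX4-VP16. After quantile normalization Pax3 was -0.0618 with DUX4-ERD and Pax7 -0.0634 with DUX4-VP16. With the receptor covariate Hif1a was 0.00841 with DUX4, and Pax3 -0.0558 and Mki67 -0.012 with DUX4-ERD. Without the 4 arrays Pax3 was -0.0788 and Mki67 -0.000165 with DUX4-ERD, and Pax7 -0.0208 and Actb -0.000217 with DUX4-VP16. In an omission of 1 mouse or array Hif1a reached 0.0685 with DUX4, Actb -0.0149 with truncated DUX4, Pax3 -0.103 and Mki67 -0.0127 with DUX4-ERD, Pax7 -0.0596 and Actb -0.00355 with DUX4-VP16 and Myf5 0.0565 with DUX4c. The cause was not tested.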

Other observations

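The tests of fibroblasts and of other genes of the mast cell protease cluster were chosen after the result was seen.

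Several gene groups held members with large changes with DUX4 although the group was not called as a list against control. Of 61 Wnt pathway genes 19 rose with DUX4, 11 fell and 31 were not called (19 and 12 adjusted over the list alone), with the secreted modulators Sfrp4 at 2.40 ± 0.14 and Sfrp1 at 1.85 ± 0.10 and the receptor Fzd4 at 1.68 ± 0.12 (camera adjusted p = 0.1). Of 61 extracellular matrix genes 15 rose, 22 fell and 24 were not called (16 and 26 over the list alone), with the protease Adamts1 at 3.25 ± 0.12, the collagen Col12a1 at 2.31 ± 0.13 and the crosslinking enzyme Lox at 1.56 ± 0.15. That list had a median of -0.173, a mean of 0.147 and a camera adjusted p = 0.782 in the lower direction. Of 46 interferon and innate immunity genes 8 rose with DUX4, 5 fell and 33 were not called (9 and 5 over the list alone), with Oasl2 at 3.83 ± 0.14, a median of -0.044, a mean of 0.096 and adjusted p = 0.54 in the higher direction. Of 44 neural and neural crest genes 7 rose, 2 fell and 35 were not called (7 and 2 over the list alone), with the adhesion molecule Cntn1 at 2.12 ± 0.13 and the microtubule protein Map2 at 1.82 ± 0.14 (adjusted p = 0.133). Of 46 genes of TGF-beta and BMP signalling 5 rose, 15 fell and 26 were not called (5 and 18 over the list alone), with adjusted p = 0.0658.

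With DUX4 against control, the lists of cell death and of early or germ cells were not called by camera. Of 39 apoptosis genes 5 rose with DUX4, 3 fell and 31 were not called (5 and 4 over the list alone), at adjusted p = 0.534. The survival factor Bcl2 rose by 1.12 ± 0.09 with DUX4, by 2.10 ± 0.09 with DUX4-VP16 and by 1.23 ± 0.09 with DUX4c, and the death receptor Fas by 1.39 ± 0.14 with DUX4. Of 40 p53 target genes 3 rose with DUX4, 13 fell and 24 were not called (4 and 13 over the list alone), at adjusted p = 0.114. Of all genes 22.4% were called with DUX4. By fry, which does not compare a list with other genes, the p53 list was lower at adjusted p = 0.0329. Of 38 pluripotency genes 4 rose with DUX4, 3 fell and 31 were not called (4 and 3 over the list alone), at adjusted p = 0.825, with Klf4 at 0.95 ± 0.09 and Esrrb at 0.94 ± 0.14. Of 55 germline genes 1 rose with DUX4, 3 fell and 51 were not called (1 and 2 over the list alone), at adjusted p = 0.485. Of the 30 measured cleavage-stage genes, out of 65 listed, 1 rose with DUX4-VP16 and 1 fell (1 and 0 over the list alone), at adjusted p = 0.4. Of 17 endothelial markers limma called 0 with DUX4 (0 over the list alone), at adjusted p = 0.636.

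Key genes not described above had small changes or calls that ended without single mice. Actb moved by 0.06 ± 0.06 with DUX4 and by 0.01 ± 0.06 with DUX4-VP16, Hif1a by -0.00 ± 0.07 with DUX4 and 0.15 ± 0.07 with truncated DUX4, and Mki67 by -0.07 ± 0.08 with DUX4, none of them called. Des changed by -0.38 ± 0.06 with DUX4-VP16, a call that ended without mouse 3. Pax7 changed by -0.31 ± 0.07 with truncated DUX4 and by 0.34 ± 0.07 with DUX4-ERD, and both calls ended without any 1 of the 3 mice. Pax3 rose by 0.40 ± 0.11 with DUX4, a call that ended without mouse 1 or mouse 2, without control array 1 or 2 and without DUX4 array 2.

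Whether a grouping by chance gives as many called genes was asked by regrouping the arrays. For each pair of groups the 6 arrays make 10 splits, too few for a share under 0.05, and the highest other split called 0 genes in each of the 9 comparisons, where 1 split, the real one, called 4472 genes with DUX4, 1834 with truncated DUX4, 1985 with DUX4-ERD, 4603 with DUX4-VP16 and 2965 with DUX4c. The real split called 3984 genes for DUX4 against DUX4c, 4042 for DUX4 against truncated DUX4, 909 for DUX4-VP16 against DUX4 and 5543 for DUX4-VP16 against DUX4-ERD. Each other split mixes arrays of both groups, so real differences between them add to its spread and lower its calls. No conclusion is drawn from the splits. For the F test over the 5 constructs only 1 of 100 arrangements of the constructs within mice, the real one, called as many as 7116 genes. That makes a grouping by chance unlikely but does not exclude it. The highest other arrangement called 3610.

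Osr2, Osr1 and Pdgfra, markers of fibroblasts and fibro-adipogenic progenitors, rose with DUX4 by 3.75 ± 0.09, 1.86 ± 0.14 and 2.81 ± 0.11 and also with DUX4-VP16. More fibroblasts in these cultures were a possible explanation, and the tables argue against it: the other 20 measured markers had a median change of -0.13 with DUX4 (upper quartile 0.031) and -0.16 with DUX4-VP16 (upper quartile -0.068). Of the abundant ones Pdgfrb fell by 0.67 and Scx by 0.87 with DUX4-VP16, while with DUX4 their falls of 0.65 and 0.59 were not called without mouse 3 (adjusted p = 0.0578 and 0.11) and Thy1 (-0.37) not without mouse 2 or mouse 3. With DUX4 Dcn, at a control signal of 9.78, was not called (-0.36, adjusted p = 0.073). Rises went the other way: the abundant Tcf4 by 1.09 with DUX4 and 1.15 with DUX4-VP16, the dim Lum by 1.33 and 1.03, and with DUX4-VP16 the abundant Prrx1 by 0.38, not called without mouse 3 (adjusted p = 0.0869). Of these 20 genes 9 had a control signal above the all-gene median of 8.19 and 4 stood in another list. A change of these genes within myoblasts stays open and was not tested.

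Mcpt1 rose more than 100-fold with truncated DUX4 and DUX4c, which led to a test for mast cells or basophils in these cultures. A set of 16 markers argues against them, with a median change of -0.072 with DUX4c (upper quartile 0) and -0.064 with truncated DUX4 (upper quartile -0.005). Cpa3, Kit and Tpsb2 were not called at control signals of 5.85, 7.15 and 7.22, and Gata2 did not rise. Of the 16, Srgn alone rose (1.13 with DUX4c and 1.00 with truncated DUX4). Mcpt8, a gene of the mast cell protease cluster that was not among the 16, went the other way. It rose from an abundant control signal of 11.16. Of these 16 genes 1 had a control signal above the all-gene median and 0 stood in another fixed list. Signal from another gene of that cluster was a further possible explanation. Of 6 measured genes Mcpt8 rose most, by 1.02 with DUX4c and 0.59 with truncated DUX4. Mcpt1 rose by 7.59 and 6.83, which argues against Mcpt8 as the source. A pair of probe sets, each with 2 symbols of the cluster, rose by 5.23 ± 0.20 and 4.82 ± 0.19 with DUX4c. With truncated DUX4 they rose by 3.45 ± 0.20 and 3.17 ± 0.19. Signal from the genes of those probe sets may contribute and stays open, because the probe sets cannot be given to 1 gene.

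A hypothesis was that neighbouring genes rise together with DUX4. Among 476 genes raised at least 2-fold with a known place, 25 neighbouring pairs of unrelated symbol were both raised, against a median of 12 in 10000 random placements matched for signal in 10 bins, of which at most a share of 0.05 had more than 18 (permutation p = 0.0011, adjusted p = 0.0073 over 10 tests). Examples are Fas and Ch25h, Ttc32 and Osr1, and Lama2 and Ptprk, which were chosen after their values were seen. The number was 22 with DUX4-VP16 (adjusted p = 0.0094), 6 with DUX4c (adjusted p = 0.0078) and 4 with DUX4-ERD (adjusted p = 0.0073), 1 with truncated DUX4 (adjusted p = 0.36), and among genes lowered 3 with DUX4-ERD (adjusted p = 0.0073), 1 with DUX4c (adjusted p = 0.14) and 0 with the others (adjusted p = 1). The 25 pairs are consistent with the hypothesis for DUX4, but functional clusters and overlapping transcripts were not tested as explanations.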
